A study of Homo sapiens with 4 samples.

How the data were processed

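RNA was sequenced from U2OS cells, a line that the sample titles spell U2O2. Cells were transfected with a control siRNA or an siRNA against NEAT1 and grown with or without 10 µM nutlin-3a. Each of the 4 combinations has 1 library. Per the labels' protocols, nutlin was added 24 h after transfection and RNA was extracted 24 h later. The labels name Illumina libraries but give neither the selection of RNA (poly(A) capture or ribosomal depletion) nor the strandedness.

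Per the submitters' processing notes, the authors used bcl2fastq 1.8.3, Bowtie2 2.0.12 and Cuffnorm 2.2.1 with the genome build hg19. The gene annotation is not given in the sources used here. Each deposited table holds 1 signal value per gene for 1 library, a non-negative estimated fragment count divided by a library size factor, and is called a normalized count in the text. This reading comes from the values. In every library the low values repeat whole multiples of 1 step, which is what 1 fragment is worth: 0.998 for the control siRNA, 1.18 for the NEAT1 siRNA, 0.910 for the control siRNA with nutlin and 0.930 for the NEAT1 siRNA with nutlin. Between 68.9% and 69.7% of the values of up to 20 fragments lay within 0.1 fragments of a whole number. The remaining values lay between whole fragments, so whole reads could not be recovered for all genes, and no count model was used. The plan made before the data were examined took the values to be FPKM. The filter planned as a mean of 1 FPKM was replaced by a mean of 20 normalized counts, and the limits planned as 5 FPKM by 100 normalized counts, before any comparison was run. Planned pseudocounts were kept.

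Each table has 86325 rows, of which 60882 have names starting with lnc- and 36515 were listed at 0 in all 4 libraries. Blanks at the end of 63332 names were removed. Of 584 genes in 26 lists fixed beforehand, 567 matched a row by symbol or older symbol. Short RNAs (2000 rows) were left out, although none reached the filter. The total of a library divided by its step gave 15319831 estimated fragments for the control siRNA, 12704201 for the NEAT1 siRNA, 16866578 for the control siRNA with nutlin and 16571950 for the NEAT1 siRNA with nutlin. A count of 0 allows up to 3 fragments, or 2.73 to 3.53 normalized counts. Ratios of NEAT1 between libraries have 95% exact binomial intervals from the estimated fragments, which cover counting error only.

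Analysis was done in R 4.3.3 with limma 3.58.1 on log2(normalized count + 1), for the 17278 rows with a mean of at least 20 over the 4 libraries (3988 of them lnc- rows). Fold changes are on this scale and understate changes of low genes. Since a group holds 1 library, a group against a group has no test. An additive model of siRNA and nutlin was fitted to the 4 libraries and tests the nutlin effect averaged over both siRNAs, and the siRNA effect averaged over both nutlin states, 2 libraries against 2 in each. It leaves 1 residual degree of freedom per gene, which holds the siRNA-by-nutlin difference together with noise. Variances were moderated with a trend on expression (prior degrees of freedom 4.30). P-values are limma's, adjusted by Benjamini-Hochberg over all rows, with a threshold of 0.05, and ± gives the standard error. Each group holds 1 library, so standard errors and p-values rest on how far an effect differs between its 2 pairs of libraries, moderated across genes. They do not measure the spread between repeated libraries or cultures, technical or biological. Nothing in the labels places the libraries in separate cultures. Effects within 1 siRNA or 1 nutlin state, and the interaction (the nutlin effect with the NEAT1 siRNA minus that with the control siRNA), have no replicate check and are given as values. Rows were counted when they differed at least 2-fold.

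Lists were tested on both averaged effects with camera (limma, preset correlation 0.01, adjusted over 25 lists). They held p53 targets by function, p53-linked long noncoding RNAs, G2/M and G1/S genes, homologous recombination, paraspeckle proteins, neighbours of NEAT1, interferon, NF-kB, integrated stress, heat shock, cholesterol, hypoxia, matrix, osteoblast, ribosomal protein, histone and housekeeping genes, and markers of epithelial, blood and neural or endothelial cells. Mitochondrially encoded genes were a further list and were not analysed here, since no row matched. Camera was repeated with the correlation estimated from the residuals. That test has 1 residual degree of freedom here, so hardly any list could pass it. A call missing there does not show that correlation between genes accounts for a list. For the interaction, the median of a list was placed among the medians of 10000 random lists of the same size matched on mean expression, and given a 95% order-statistic interval over its genes, which does not cover the difference between repeated cultures.

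Genes were named by a rule fixed before the data were examined: NEAT1, MDM2 and CDKN1A among others; the 12 largest rises and 8 largest falls past the threshold with nutlin, and 10 each way with the NEAT1 siRNA, with the same direction in both arms; the 8 largest interactions each way among rows reaching 100 normalized counts in 1 library; the 4 most negative and 4 most positive interactions among p53 targets; and up to 4 members per list with the largest change. Rows named lnc- or LOC were not named. MX1, IFNB1, MCM3, RAD51C, SCARNA2, SCARNA10 and lnc-FRMD8-1 fall outside the rule and were chosen after their values were seen.

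Simulated libraries gave all genes 1 dispersion (0.0082), set from the median spread of the real ones, and no siRNA-by-nutlin difference. In them the averaged nutlin comparison recovered 58.2% of genes changed 1.5-fold and 91.9% of those changed 2-fold. It recovered 100% of those changed 4-fold, over 17084 rows. The averaged siRNA comparison recovered 43.9%, 87.9% and 100%, over 17082 rows. Unchanged genes made up 3.05% and 3.80% of the calls. Real genes differ in spread and can differ between arms, so these rates need not hold for the real libraries. Other settings chosen before the data were examined were another pseudocount, scaling by median ratios, no filter or a stricter one, short RNAs kept, limma without the trend or with robust moderation, a size of 1.5-fold, other definitions of induced genes and the estimated correlation. Added after seeing the data were a pseudocount of 20, a mean of at least 1, voom weights, and leaving out lnc- rows.

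For sequence motifs, the longest annotated 3′ UTR per gene symbol was taken from GENCODE release 29, a different build from the deposited tables, so that no coordinates are given. It was found for 10256 (84.7%) of 12110 rows with a mean of at least 100. After regression on log UTR length and GC content, with residuals limited to ±2, a score of each 7-mer present in at least 50 genes compared genes with and without it (Python 3.11.15, NumPy 2.4.6, pandas 2.3.3). In simulated values, a shift of 0.1 (log2) of 500 genes that shared a 7-mer placed that 7-mer at rank 1 of 16183. Figures were drawn with Matplotlib 3.10.9.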

Results

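The series asked how depletion of NEAT1, the long noncoding RNA around which nuclear paraspeckles form, changes the transcription that p53 activates. U2OS is a human osteosarcoma line with wild-type p53. Nutlin-3a keeps the ubiquitin ligase MDM2 from binding p53 and so stabilises p53 without DNA damage. Expression was measured by RNA sequencing in 4 libraries: control siRNA, NEAT1 siRNA, control siRNA with 10 µM nutlin and NEAT1 siRNA with 10 µM nutlin. Each group has 1 library, of 12704201 to 16866578 estimated fragments. Values are normalized counts, and differences are log2(normalized count + 1) unless stated otherwise.

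NEAT1 itself was measured at 5148 normalized counts with the control siRNA and 4277 with the NEAT1 siRNA, a ratio of 0.831 (95% counting interval 0.796 to 0.867). With nutlin it was measured at 16467 and 9429, a ratio of 0.573 (0.559 to 0.587). The averaged siRNA effect of -0.54 ± 0.13 did not pass the threshold (limma, adjusted p = 0.133; lower in both nutlin states). NEAT1 rose with nutlin by 1.41 ± 0.13 on average (limma, adjusted p = 0.00146), by 1.68 (3.20-fold) with the control siRNA and 1.14 with the NEAT1 siRNA. The library labelled NEAT1 siRNA with nutlin therefore held 1.83 times (1.77 to 1.89) the NEAT1 of the untreated control. These values count the whole locus and do not separate its short, polyadenylated transcript from the long one that has no poly(A) tail. RPPH1, the RNA of RNase P, which has no poly(A) tail either, was listed at 118 with the control siRNA and 1186 with the NEAT1 siRNA, and the small Cajal body RNA SCARNA10 at 5.99 and 56.4. With nutlin RPPH1 was at 3.64 and 6.39 and SCARNA10 at 0.910 and 1.86.

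MDM2, a p53 target and negative regulator of p53, rose with nutlin by 2.99 ± 0.07 (limma, adjusted p = 2.72e-04), an effect of 2.99 with the control siRNA and 2.98 with the NEAT1 siRNA. Its level was lower with the NEAT1 siRNA in both states, at 1927 against 2735 without nutlin and 15257 against 21751 with it (-0.51 ± 0.07, limma, adjusted p = 0.0372). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose by 2.75 ± 0.10 (limma, adjusted p = 3.01e-04), 5.96-fold with the control siRNA and 7.56-fold with the NEAT1 siRNA.

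**Figure D1:**
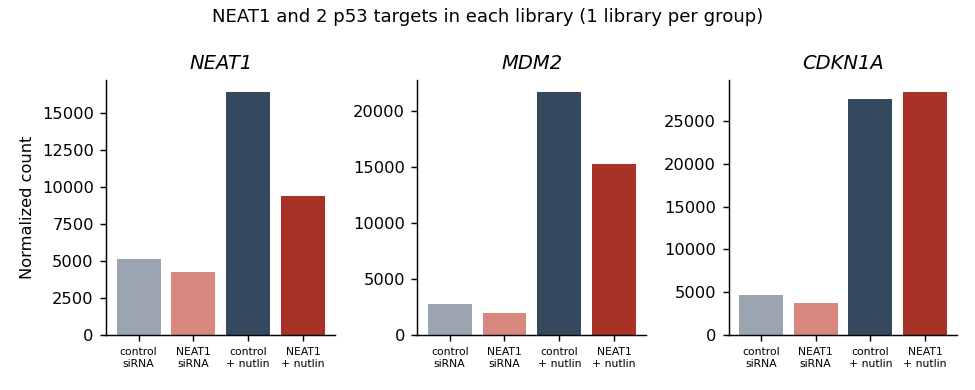
Normalized counts (linear axis from 0) of NEAT1, MDM2 and CDKN1A, 1 bar per library and no error bar, since each group has 1 library. NEAT1 stood at 16467 with nutlin and the control siRNA and at 9429 with nutlin and the NEAT1 siRNA, while CDKN1A stood at 27639 and 28460.

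Nutlin raised the p53 target lists. Of 109 p53 targets measured, 88 rose and 5 fell. In the cell cycle arrest list 14 of 16 rose, among them BTG2 (2.69 ± 0.08), an antiproliferative cofactor, and TP53INP1 (2.54 ± 0.08). In the apoptosis list 16 of 18 rose, including the death receptor FAS (2.97 ± 0.08), the oxidoreductase TP53I3 (2.96 ± 0.08), ZMAT3 (2.62 ± 0.07) and the autophagy regulator DRAM1 (2.30 ± 0.09). In the metabolism list 13 of 16 rose, including the glutaminase GLS2 (4.77 ± 0.35) and the ferredoxin reductase FDXR (2.35 ± 0.07). Among other direct targets 39 of 48 rose and 3 fell, with the transcription factor GRHL3 (4.80 ± 0.20), PADI4 (4.54 ± 0.22) and the stress cytokine GDF15 (3.87 ± 0.12) leading. The genes of DNA repair and nucleotide supply went both ways, 6 of 11 rising and 2 falling: RRM2B, the p53-inducible ribonucleotide reductase subunit, rose by 2.27 ± 0.07. Of 9 p53-linked long noncoding RNAs 6 rose, such as LINC01021 (1.85 ± 0.11) and PVT1 (1.36 ± 0.09). Adjusted over the list alone, the counts of rises were 15, 17, 13, 39, 6 and 8 in this order of lists. Every gene with a value here passed the threshold in limma (adjusted p 2.72e-04 to 7.36e-04), and the direction was the same in both siRNA arms. Camera (limma) called the lists of cell cycle arrest (adjusted p = 6.17e-11), apoptosis (adjusted p = 6.17e-11), metabolism (adjusted p = 1.73e-08), other direct targets (adjusted p = 1.49e-16) and noncoding RNAs (adjusted p = 5.66e-04) but not DNA repair (adjusted p = 0.0998). With an estimated correlation none was called (camera, limma, adjusted p = 0.511 for each), but with 1 residual degree of freedom that test could hardly call any list.

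The 12 named rises were mostly of genes near the floor without nutlin, so their counts are given and not folds. TREM2, a receptor known from myeloid cells, was measured at no more than 3.53 normalized counts without nutlin and at 316 and 422 with it. Of 3 named genes of the late cornified envelope of the epidermis, LCE1F was listed at 0 without nutlin and at 62.8 and 78.2 with it, LCE1B at 0 and 1.18 against 73.7 and 99.6, and LCE1C at 0 and 1.18 without nutlin and up to 110 with it. RNASE7, an antimicrobial ribonuclease of skin, went from 0.998 and 0 to 83.7 and 112, and CLCA2, a regulator of chloride channels, from no more than 4.70 to 182 and 244. The chemokine CCL3 stood at 4.99 and 3.53 without nutlin and 261 and 243 with it. CYP4F3, PLCH2, LINC01629 and the adhesion gene CEACAM1 also passed the threshold. CEACAM1 was practically 0 (2.94e-14) in the untreated NEAT1 siRNA library against 14.3 in the untreated control, and its call was lost with robust moderation (limma). ESM1, a secreted proteoglycan, rose by 5.08 ± 0.29 (limma, adjusted p = 4.78e-04), from 43.9 and 37.6 to 991 and 2001 normalized counts.

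Genes of the cell cycle fell with nutlin. Of 35 measured G2/M and mitosis genes 35 fell, including the kinases PLK1 (-4.28 ± 0.40) and BUB1B (-4.21 ± 0.39), the proliferation marker MKI67 (-4.23 ± 0.52) and the kinetochore gene NDC80 (-4.16 ± 0.52). Of 36 G1/S and replication genes 35 fell, including the cyclin CCNE2, the ribonucleotide reductase subunit RRM2 (-4.15 ± 0.35) and E2F1 (-4.12 ± 0.29). Of 24 genes of homologous recombination and the Fanconi pathway 20 fell, among them EXO1 (-3.84 ± 0.35), and RAD51C rose by 0.62. Each of these falls passed the threshold in limma (adjusted p 6.68e-04 to 0.00314) and was seen in both siRNA arms. Adjusted over the list alone, 35, 35 and 20 fell. Camera (limma) called the lists G2/M (adjusted p = 2.89e-16), G1/S (adjusted p = 1.06e-20) and homologous recombination (adjusted p = 3.40e-10). With an estimated correlation and 1 residual degree of freedom none of them passed (camera, limma, adjusted p = 0.511 for each), which does not decide these calls. Among the named falls, E2F2 went from 857 and 619 normalized counts without nutlin to 45.5 and 1.86 with it, FAM111B from 1861 and 1290 to no more than 92.8, and CCNE2 from 317 and 279 to 15.2 and 2.79. LINC00639, the smooth muscle coactivator MYOCD, SHISA3 and RPPH1 also fell (limma, adjusted p below the threshold) and had no more than 6.39 normalized counts in any nutlin library. The calls of E2F2 and FAM111B were lost with robust moderation (limma).

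Of 13 replication-dependent histone genes 10 fell with nutlin (adjusted over the list alone, 11; camera, limma, adjusted p = 7.95e-05, and adjusted p = 0.604 with an estimated correlation). That correlation was 1 against the preset 0.01, so the p-value with the preset may be too small. Histone mRNAs carry no poly(A) tail, and their median differed by 0.92 between the untreated NEAT1 siRNA library, in which RPPH1 and SCARNA10 were also higher, and the untreated control. Both RNAs were also lower with nutlin in both arms, RPPH1 at 118 and 1186 without nutlin against 3.64 and 6.39 with it, and SCARNA10 at 5.99 and 56.4 against 0.910 and 1.86. HIST1H1E, for example, fell with nutlin by 3.02 ± 0.81 (limma, adjusted p = 0.0359). Paraspeckle proteins fell too, 19 of 26 with none rising (adjusted over the list alone, 19 fell and 1 rose). PSPC1 fell by 0.73 ± 0.08 and HNRNPUL1 by 0.87 ± 0.07 (limma, adjusted p 9.01e-04 to 0.00246; camera, limma, adjusted p = 9.63e-07, and adjusted p = 0.511 with an estimated correlation). The median of the list was -0.45 with the control siRNA and -0.44 with the NEAT1 siRNA. Among 16 neighbours of NEAT1 on chromosome 11, 4 rose and 6 fell (adjusted over the list alone, 6 and 6; camera, limma, adjusted p = 0.780). MALAT1, the noncoding RNA beside NEAT1, rose by 0.77 ± 0.13 (limma, adjusted p = 0.00917).

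Over all 17278 rows, 3376 rose and 3317 fell with nutlin (limma, adjusted p below the threshold of 0.05), and of these 1203 and 1326 changed at least 2-fold. Without the trend limma called 1709 rises and 1736 falls, and with no filter on low values it called 0 in either direction, with 9515 rows at an unadjusted p under 0.05.

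The question of the series is whether the nutlin effect differs between the siRNA arms. For p53 targets it differed little, between arms in which NEAT1 was measured as only partly lower. With the NEAT1 siRNA, NEAT1 counted over the whole locus stood at 0.831 of the control without nutlin and 0.573 with it. RPPH1, which has no poly(A) tail, stood at 10.1 times the control without nutlin and 1.76 times with it. Whether the capture of such RNAs differed between libraries was not tested, so the NEAT1 ratios need not equal the depletion. What a stronger depletion would do was not measured. The median nutlin effect over the 109 targets was 1.41 (2.66-fold) with the control siRNA and 1.48 (2.78-fold) with the NEAT1 siRNA. The median difference between arms was 0.01 (95% interval over genes -0.05 to 0.07, or 0.966-fold to 1.05-fold), 53 of 109 lay below 0, and random lists matched on expression placed it at percentile 18.4. For the 88 targets that rose, the medians were 1.74 and 1.72, but these passed a test that favours equal effects in both arms. The most negative differences were those of CASP1 (-1.10), the pantothenate kinase PANK1 (-0.77), CMBL (-0.69) and KANK3 (-0.67), and the most positive those of GLS2 (1.22), VWCE (effects of 0.34 and 1.34), FDX1 (0.61) and TGFA (0.57). CASP1, GLS2, KANK3 and VWCE had fewer than 50 normalized counts in at least 1 library. NEAT1 itself had a difference of -0.54. These differences were not tested, since each rests on 4 single libraries.

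Cell cycle genes differed more between arms. The median nutlin effect on the G2/M genes was -2.77 with the control siRNA and -4.54 with the NEAT1 siRNA, a median difference of -1.84 (95% interval over genes -1.94 to -1.70), and all 35 genes lay below 0. MKI67 was measured at 12667 and 11164 normalized counts without nutlin, then at 1525 with nutlin and the control siRNA and 261 with nutlin and the NEAT1 siRNA. NDC80 stood at 361 and 59.2 in these nutlin libraries and PLK1 at 190 and 72.6. For G1/S genes the medians were -2.51 and -3.41 (median difference -0.78, -0.94 to -0.45, 32 of 36 below 0), and for homologous recombination -2.38 and -3.29 (median difference -0.70, -1.13 to -0.38, 22 of 24 below 0). Histone genes had a median difference of -1.32 (-2.23 to -1.03), with a median siRNA effect of 0.92 without nutlin and -0.43 with it, and RPPH1, which has no poly(A) tail either, had a difference of -2.65. None of 10000 random lists, matched on expression but not on the nutlin effect, had as low a median as any of these 4 lists. At the other end, cholesterol genes had a median difference of 0.22 (0.15 to 0.28, 2 of 23 below 0, percentile 100 after rounding) and NF-kB genes of 0.18 (-0.16 to 0.80, 7 of 15 below 0, percentile 97.9). Random lists hold unrelated genes, while genes of a list can move together, so these placements do not tell whether a difference would recur. For comparison, all rows lowered at least 2-fold on average with nutlin had a median difference of -0.30. The differences of these lists, too, have no replicate check.

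**Figure D2:**
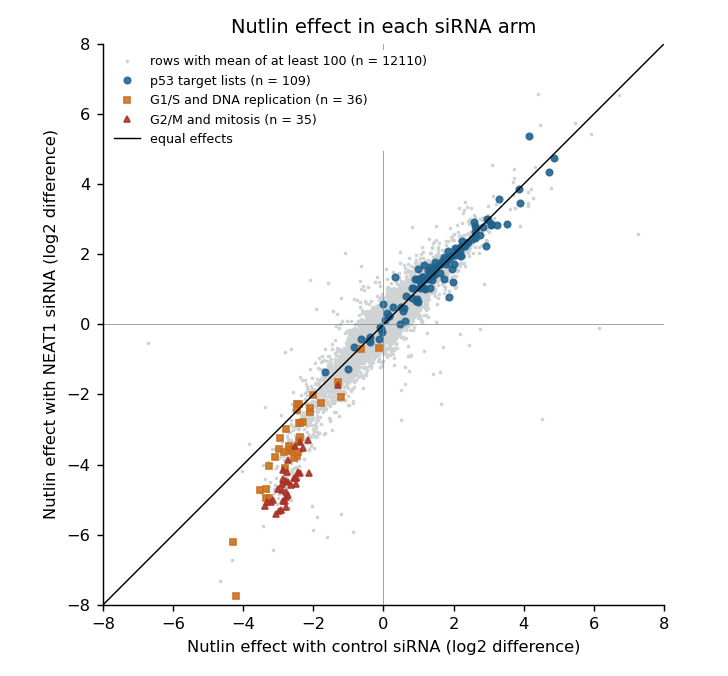
Nutlin effect (log2 difference) with the control siRNA (x axis) and with the NEAT1 siRNA (y axis), 1 point per row with a mean of at least 100 normalized counts, with p53 targets, G1/S and G2/M genes in colour. P53 targets follow the line of equal effects, while the 35 G2/M genes lie below it. Of 12110 rows, 4 fall outside the axes.

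**Figure D3:**
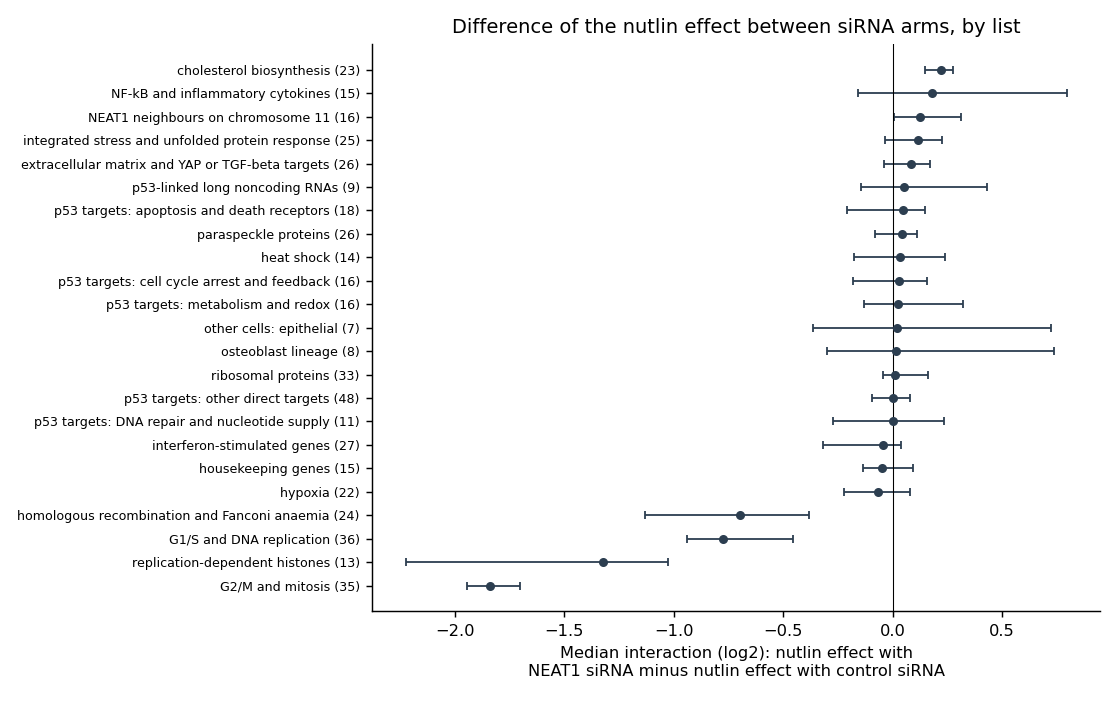
Median difference of the nutlin effect between siRNA arms (log2) for each list of at least 6 genes, with the number of genes in parentheses. Bars are 95% order-statistic intervals over the genes of a list and do not cover the difference between repeated cultures. The lists G2/M, histones, G1/S and homologous recombination lie at medians from -1.84 to -0.70.

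Across all rows, 1446 were at least 2-fold higher and 1487 at least 2-fold lower with nutlin under the control siRNA, against 1469 and 1643 under the NEAT1 siRNA. Both arms shared 1012 of the higher rows (123 expected from independent lists) and 1143 of the lower rows (141 expected), and they have no library in common. Opposite changes were seen in 29 rows (higher with the control siRNA, 138 expected) and 26 rows (lower with it, 126 expected). Nutlin effects correlated across genes with Pearson's r of 0.755 and Spearman's rho of 0.775, where genes are not independent replicates. The difference between arms was at least 2-fold upward in 420 rows and downward in 683. Set on an equal footing for noise, 2804 rows reached 2-fold in the averaged nutlin effect, 504 in the averaged siRNA effect and 271 in the difference between arms scaled to the same noise. Among 1343 rows induced at least 2-fold on average, the median difference between arms was 0.03 (-0.00 to 0.06) and 47.4% lay below 0. Among 1461 rows lowered at least 2-fold it was -0.30 (-0.34 to -0.26), with 71.6% below 0. Choosing induced rows by the control arm alone gave a median of -0.17, and by the NEAT1 siRNA arm alone 0.19, as choosing rows on a noisy arm brings about.

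Interferon-stimulated genes were lower with the NEAT1 siRNA. Of 27 measured, 26 fell in the averaged siRNA effect (adjusted over the list alone, 26; camera, limma, adjusted p = 1.16e-38, and adjusted p = 0.733 with an estimated correlation). The median was -1.65 without nutlin and -1.77 with it. OAS2, a sensor of double-stranded RNA, was measured at 2449 with the control siRNA and 241 with the NEAT1 siRNA, and at 3194 and 310 with nutlin (-3.35 ± 0.08, limma, adjusted p = 0.00130). Its relative OAS1 fell by 2.63 ± 0.08, the antiviral GTPase MX2 by 3.38 ± 0.16, IFIT1 by 2.53 ± 0.09, RSAD2 (viperin) by 2.55 ± 0.18 and IFI27 by 2.91 ± 0.12 (limma, adjusted p 0.00262 to 0.00865). IFITM1 and CMPK2, other interferon-induced genes, fell by 3.22 ± 0.27 and 2.72 ± 0.25 (limma, adjusted p = 0.0134 and 0.0159). MX1 did not pass the threshold (-0.24), at 37.1 and 37.6 normalized counts without nutlin. B2M, a housekeeping gene that interferon also raises, fell by 0.76 ± 0.07 (limma, adjusted p = 0.0159). Transcripts of interferon beta (IFNB1) were at 0.998 normalized counts in the untreated control and listed at 0 in the other 3 libraries.

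Other genes were named by a rule that required the same direction in both nutlin states. The test also favours equal effects, since its 1 residual degree of freedom holds the difference between states. Their agreement is therefore no separate result. NEGR1, a neuronal adhesion gene, was 5.25-fold and 3.54-fold higher with the NEAT1 siRNA without and with nutlin (2.11 ± 0.15, limma, adjusted p = 0.00865). PRMT6, an arginine methyltransferase, rose by 1.88 ± 0.11, the kinesin KIF3B by 1.76 ± 0.07, the splicing regulator PTBP1 by 1.39 ± 0.07 and the p53 target TRIAP1 by 1.56 ± 0.11 (limma, adjusted p 0.00267 to 0.00865). The Wnt receptor FZD6 (limma, adjusted p = 0.00486) rose too, and SUMF1, CACNA2D1, HIBCH and C18orf32 rose by 1.45 to 1.73 (limma, adjusted p 0.00964 to 0.0161). HHIP-AS1 stood at 34.8 and 0.0860 without nutlin and 65.8 and 0.696 with it (limma, adjusted p = 0.0394, but adjusted p = 0.0889 and no call with a pseudocount of 0.1), and its reads cannot be told from those of its antisense partner where strand is not counted.

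**Figure D4:**
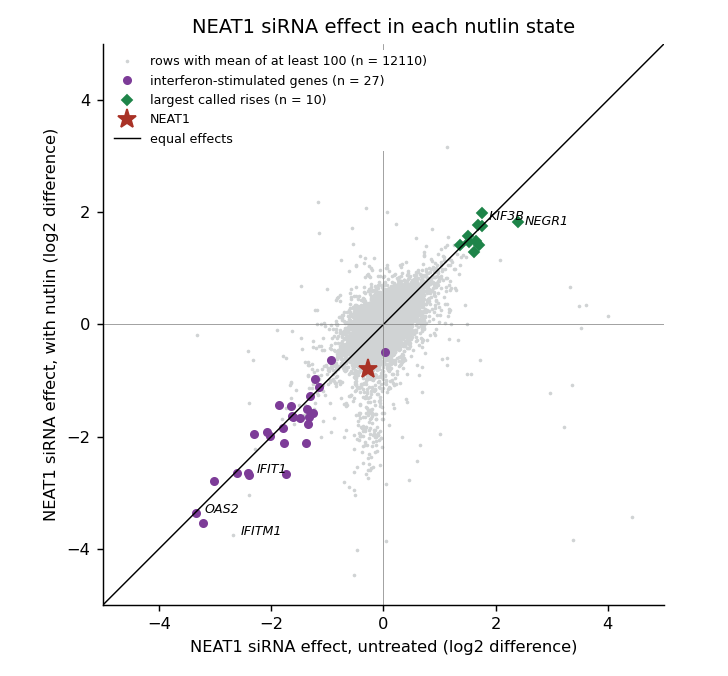
NEAT1 siRNA effect (log2 difference) without nutlin (x axis) and with nutlin (y axis), 1 point per row with a mean of at least 100 normalized counts, with 27 interferon-stimulated genes, the 10 named rises and NEAT1 marked. Interferon-stimulated genes lie near the line of equal effects, with medians of -1.65 and -1.77. Of 12110 rows, 10 fall outside the axes.

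Most p53 targets did not pass the threshold for the siRNA effect: of 109, APAF1 (0.88) and TRIAP1 (1.56) rose, and MDM2 (-0.51), TRIM22 (-0.52) and PCNA (-0.49) fell. By list, camera (limma) called DNA repair and nucleotide supply lower (adjusted p = 0.00222, but adjusted p = 0.733 with an estimated correlation) and none of cell cycle arrest (adjusted p = 0.294), apoptosis (adjusted p = 0.531), metabolism (adjusted p = 0.733), other direct targets (adjusted p = 0.531) and noncoding RNAs (adjusted p = 0.481). Adjusted over the list alone, 3 arrest genes rose and 3 fell, 3 apoptosis genes rose, 2 repair genes fell and 1 noncoding RNA fell. Camera (limma) also called G2/M (adjusted p = 9.25e-10), G1/S (adjusted p = 2.10e-12) and homologous recombination (adjusted p = 1.54e-05) lower, although only MCM3 (-0.62) passed by itself in these 3 lists, and 25 G1/S genes did so adjusted over the list alone. With an estimated correlation and 1 residual degree of freedom none of these 3 lists passed (camera, limma, adjusted p = 0.733 for each), which does not decide their calls. Their medians were small without nutlin, at -0.15, -0.34 and -0.25, and -1.98, -0.93 and -0.96 with it. Of 26 paraspeckle proteins TARDBP (0.56) rose and none fell (adjusted over the list alone, 1 and 1; camera, limma, adjusted p = 0.645). None of the 16 neighbours of NEAT1 passed (camera, limma, adjusted p = 0.815), and MALAT1 was at 1077 and 1705 normalized counts without nutlin and 2204 and 2433 with it.

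In all, 183 rows rose and 169 fell with the NEAT1 siRNA (limma), 43 and 69 of them at least 2-fold, and 3250 rows had an unadjusted p under 0.05 where 864 would by chance. Without the trend limma called 0 rows (2378 at an unadjusted p under 0.05), with no filter 0 (4245), and with robust moderation 364 rises and 333 falls. Within the untreated libraries 367 rows were at least 2-fold higher and 326 lower, and within the nutlin libraries 259 and 551. Both states shared 75 higher rows (5.50 expected from independent lists) and 85 lower rows (10.4 expected). Opposite changes also exceeded independence, with 32 rows higher without nutlin and lower with it (11.7 expected) and 30 the other way (4.89 expected). The states have no library in common. Effects correlated across genes with r of 0.193 and rho of 0.361.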

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

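Tests of scaling, of p53 target strength and of the NEAT1 amount were chosen after the results they address were seen. Those of low values and of the control siRNA were written down beforehand.

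Some results have opposite signs in the arms compared, each arm being 1 difference between single libraries, so these contrasts were not tested. Median effects of the NEAT1 siRNA without and with nutlin were -0.02 and 0.03 for p53 targets of apoptosis (difference 0.0511), -0.09 and 0.07 for the neighbours of NEAT1 (0.16), -0.00 and 0.14 for heat shock genes (0.15), and 0.92 and -0.43 for replication-dependent histones (-1.35). Median effects of nutlin with the control and with the NEAT1 siRNA were -0.12 and 0.04 for the neighbours of NEAT1 (0.16) and -0.06 and 0.17 for integrated stress genes (0.23). Among the genes named for the difference of nutlin effects, FDX1 had effects of -0.03 and 0.59 (difference 0.61, not tested). The differences of the rest were not tested either: XAGE1E (-11.11), C9orf69 (-7.22), BIVM-ERCC5 (-6.25), FRMD6-AS1 (-3.59), POLDIP2 (8.31), ZNF883 (7.99), MAP3K14 (7.77) and RPL7 (3.30). The ribosomal precursor RNA45S5 had a difference of 16.52 that is doubted and not relied on, since it rests on a listed 0 in the untreated NEAT1 siRNA library against 64273 to 86095 normalized counts in the other 3. XAGE1E, POLDIP2, ZNF883, MAP3K14 and BIVM-ERCC5 each combine a value below 1 in at least 1 library with over 100 in another. The remaining genes of the same rule were DCP1A (-6.96), FAM72D (-6.09), HIST1H2AH (-4.49), E2F2 (-3.55), NUDT4P2 (7.11), RECQL4 (6.17) and CEACAM1 (3.59), each of which had at least 1 library below 10 normalized counts.

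Cell cycle genes were lower under nutlin with the NEAT1 siRNA than with the control siRNA, by a median of -1.84 over 35 G2/M genes. Scaling of the libraries is argued against, since a factor shared by a library shifts all genes alike and the list lay at -1.85 (-1.96 to -1.72) relative to the other genes with a mean of at least 100 normalized counts. Low values and the pseudocount are argued against by the 41 G2/M and G1/S genes with a mean of at least 1000 normalized counts, whose median was -1.60 (-1.79 to -0.97). A stronger response of p53 targets as a set is argued against at the level of mRNA. The interval of their median difference ends at 0.0673 for the 88 targets that rose and at 0.0665 for all 109 measured. The 88 passed a test that favours equal effects in both arms, so the argument rests on the 109. Single targets that act on the cell cycle are not covered: CDKN1A had a difference of 0.34, and E2F7 stood at 2603 and 3599 normalized counts with nutlin (difference 0.11). Such single targets, a difference between the cultures in density, timing or transfection, an effect of either siRNA on other genes, and NEAT1 itself stay open, since each arm has 1 nutlin library.

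Interferon-stimulated genes were lower with the NEAT1 siRNA in both nutlin states. Scaling of the libraries is argued against, since the list lay at -1.62 (-2.04 to -1.32) or lower relative to the other genes with a mean of at least 100 normalized counts. The amount of NEAT1 counted over the whole locus is argued against as the sole cause: the NEAT1 siRNA library with nutlin held 1.83 times the NEAT1 of the untreated control, yet its median interferon gene differed by -1.54 (-1.94 to -0.89), and nutlin moved the list by 0.23 in either arm while NEAT1 rose 3.20-fold with the control siRNA. Whether the control siRNA raised these genes or the NEAT1 siRNA lowered them cannot be told apart, because 0 of the 4 libraries had no siRNA. An effect of NEAT1 on interferon genes through one of its isoforms remains an untested biological explanation.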

How the results depend on the processing

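The alternatives with a pseudocount of 20, a mean of at least 1, voom weights or lnc- rows left out were chosen after seeing the data. No paired analysis was possible because each group has 1 library and the labels carry no replicate numbers. Leaving out a library was not possible as a test, since 3 libraries leave no residual degrees of freedom for 3 coefficients. Median-ratio scaling, whose factors of 0.997 to 1.01 changed the values little, and a pseudocount of 0.1 moved none of the counts and medians below past their limits, and keeping short RNAs changed no tested row. Of the 20 genes named for nutlin, 184 of 209 calls under alternatives were kept, and of the 20 named for the NEAT1 siRNA 178 of 219, with 0 reversed. Lost calls came from removing the filter, from limma without the trend, from robust moderation (CEACAM1, E2F2 and FAM111B) and from a pseudocount of 0.1 (HHIP-AS1). NEAT1's averaged siRNA effect also missed the threshold with a pseudocount of 0.1, with median-ratio scaling and with a pseudocount of 20 (limma, adjusted p = 0.130, 0.110 and 0.0836).

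With no filter, limma called 0 rises and 0 falls for nutlin and 0 and 0 for the NEAT1 siRNA, and the cause was not tested. Prior degrees of freedom were 0.809 there instead of 4.30, so variances were moderated less across genes. The smallest adjusted p was 0.154 for nutlin and 0.48 for the NEAT1 siRNA (limma). Rows at least 2-fold higher and lower were then 6050 and 5606 for nutlin with the control siRNA, 5945 and 7954 for nutlin with the NEAT1 siRNA, 6184 and 4055 for the siRNA untreated, 3448 and 4174 for the siRNA with nutlin, and 6001 and 8026 for the difference between arms. In the same order, a mean of at least 1 gave 4787 and 4574, 4776 and 5174, 3370 and 2917, 2455 and 3035, and 3985 and 4816, and a mean of at least 100 gave 743 and 874, 819 and 940, 87 and 107, 73 and 281, and 61 and 208. A size of 1.5-fold gave 2946 and 2886, 2940 and 2998, 1151 and 1014, 971 and 1370, and 1130 and 1646. These counts follow from the number of rows and the size itself. A pseudocount of 20 gave 141 and 153 for the siRNA untreated, 111 and 297 with nutlin, and 170 and 286 for the difference between arms. Without lnc- rows there were 934 higher rows for nutlin with the control siRNA, 166 higher and 158 lower for the siRNA untreated, 112 higher for the siRNA with nutlin, and 147 higher and 360 lower for the difference between arms.

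Limma without the trend called 1709 rises and 1736 falls for nutlin and 0 and 0 for the NEAT1 siRNA. For the NEAT1 siRNA, robust moderation gave 364 rises and 333 falls, a pseudocount of 20 gave 311 and 320, and voom weights 344 and 285. The cause of these shifts was not tested. Prior degrees of freedom were 1.84 without the trend, 5.39 with a pseudocount of 20 and 5.24 with voom weights, against 4.30 in the main setting. With an estimated correlation, camera called 0 lists higher and 0 lower for nutlin, and 0 and 0 for the NEAT1 siRNA. With 1 residual degree of freedom that test could hardly call any list. The median difference between arms of induced rows was 0.0668 (43.2% below 0) with a mean of at least 100, -0.17 (63.7%) when chosen by the control arm, 0.19 (33.2%) when chosen by the NEAT1 siRNA arm, and -0.00260 at 4-fold induction. For G2/M genes it was -1.60 with a pseudocount of 20, which shrinks low values by construction. Depth limits what low genes show: 1 fragment was worth 0.910 to 1.18 normalized counts, and folds of genes under about 20 normalized counts in a library rest on few fragments.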

Other observations

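Of 26 genes of the extracellular matrix and of YAP or TGF-beta signalling, 14 rose and 4 fell with nutlin (adjusted over the list alone, 15 and 4; camera, limma, adjusted p = 0.00457, and adjusted p = 0.511 with an estimated correlation). ANKRD1 rose by 2.32 ± 0.07 and smooth muscle actin ACTA2 7.07-fold and 7.91-fold in the control and NEAT1 siRNA arms, whereas the collagen COL3A1 fell by 2.75 ± 0.11 (limma, adjusted p 2.72e-04 to 3.58e-04). With the NEAT1 siRNA 2 of 26 rose and 24 were not called: COL3A1 (1.22 ± 0.11) and the metalloproteinase MMP3 (0.82 ± 0.10) rose (limma, adjusted p = 0.0159 and 0.0292; adjusted over the list alone, 12 rose and 3 fell; camera, limma, adjusted p = 0.00629, and adjusted p = 0.733 with an estimated correlation). Of 23 genes of cholesterol synthesis INSIG1 (0.85 ± 0.10, limma, adjusted p = 0.0271) rose with the NEAT1 siRNA (adjusted over the list alone, 6; camera, limma, adjusted p = 1.41e-05, and adjusted p = 0.733 with an estimated correlation). With nutlin 7 of these rose and 4 fell (camera, limma, adjusted p = 0.626). The estimated correlation of the cholesterol list was 0.668 against the preset 0.01, so its p-values with the preset may be too small. Hypoxia genes showed no list call (camera, limma, adjusted p = 0.541 and 0.210), although P4HA2 (1.11 ± 0.07) and NDRG1 (0.93 ± 0.07) rose with the NEAT1 siRNA (limma, adjusted p = 0.00703 and 0.0108) and LOX fell with nutlin by 1.63 ± 0.09 (limma, adjusted p = 4.17e-04). With nutlin NF-kB genes rose as a list (6 of 15, BIRC3 by 2.07 ± 0.19; camera, limma, adjusted p = 0.0245), as did ribosomal proteins (9 of 33, RPS19 by 0.71 ± 0.07; adjusted p = 0.00497) and interferon-stimulated genes (10 of 27, 1 falling, IFIT2 by 1.32 ± 0.09; adjusted p = 0.0147), while heat shock genes fell (8 of 14, 1 rising, HSPA1A by 1.16 ± 0.09; adjusted p = 0.0174). With an estimated correlation and 1 residual degree of freedom none of these 4 lists passed (camera, limma, adjusted p = 0.511 for each), which does not decide their calls.

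The other lists were not called by camera (limma). Of 25 integrated stress genes 8 rose and 4 fell with nutlin, ATF3 by 1.59 ± 0.11 among the rises (list adjusted p = 0.474), and MTHFD2 and SEL1L rose with the NEAT1 siRNA (list adjusted p = 0.868). Of 8 osteoblast genes 2 rose and 3 fell with nutlin (list adjusted p = 0.806), ALPL, the alkaline phosphatase of bone, rising by 1.58 ± 0.14, and 0 passed with the NEAT1 siRNA (list adjusted p = 0.868). Of 15 housekeeping genes 1 rose and 6 fell with nutlin (list adjusted p = 0.0715). With the NEAT1 siRNA the NF-kB, ribosomal protein, heat shock and histone lists were not called (adjusted p = 0.244, 0.0621, 0.210 and 0.258), nor were housekeeping genes (adjusted p = 0.531). Markers of other cells were few: 7 of 14 epithelial genes were measured (list adjusted p = 0.746 for nutlin), 1 of 14 blood genes, LCP1, which rose with nutlin by 1.40 ± 0.14 (list adjusted p = 0.138), and 4 of 12 neural or endothelial genes (list adjusted p = 0.780).

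The ratio of the untreated NEAT1 siRNA library to the untreated control was 10.1 for RPPH1, 7.58 for SCARNA2 and 9.42 for SCARNA10, against 1.76 for RPPH1 in the nutlin libraries, where SCARNA2 was listed at 0. The neighbouring locus row lnc-FRMD8-1 stood at 25.7 and 36.0 normalized counts without nutlin and 96.8 and 43.2 with it. These RNAs were chosen after their values were seen.

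Sequence motifs in 3′ UTRs went with the siRNA effect, and the shares and medians given for them were chosen after the scores were seen. Of 16183 7-mers, ACCTTGT had the largest absolute score in the untreated comparison (13.6), followed by the overlapping CCTTGTA (13.1), against a highest absolute score of 4.56 in 20 shuffles across genes. Genes with ACCTTGT were higher with the NEAT1 siRNA, at a median of 0.04 for 1456 genes with a site and -0.05 for 8800 without. A site was present in 74 of 163 genes called higher (45.4%), 17 of 149 called lower (11.4%) and 1365 of 9944 not called (13.7%). TRIAP1, SUMF1, PTBP1 and NEGR1 carry it, while KIF3B, PRMT6, CACNA2D1, HIBCH, FZD6 and C18orf32 do not. Among genes that fell with the NEAT1 siRNA, RSAD2 carries 1 site of ACCTTGT and MDM2 2, and CTTAGAA has 3 sites in MDM2 but also 2 in NEGR1, which rose. The 3′ UTRs of MDM2 and NEGR1 are long (10837 and 11506 bases), so sites by chance are likelier there. Unlike the scores, the shares of genes with a site are not adjusted for UTR length or GC content. CTTAGAA had the lowest score in both nutlin states (-8.97 and -6.04) and was present in 61 of 149 genes called lower (40.9%) against 28 of 163 called higher (17.2%), whereas CTAAGAA went with higher values (10.9 and 8.96). For the nutlin effect the top absolute score was 3.83 with the control siRNA and 4.84 with the NEAT1 siRNA, with shuffled maxima of 4.75 and 4.47.

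The hypothesis, whose test by rank was written down before any motif was scored, is that either siRNA repressed mRNAs whose 3′ UTR matches its seed. The 7-mer first in the untreated comparison, ACCTTGT, ranked 2 of 16183 with nutlin, in libraries not shared with the untreated comparison (score 10.6). Its direction is what repression by the control siRNA would give, and that of CTTAGAA what repression by the NEAT1 siRNA would give. CTAAGAA ranked 3 by absolute score in both states, ahead of CTTAGAA at 5 and 7. It went with higher values, like ACCTTGT, but differs from it in sequence, so a single seed would not cover both. Of 25 interferon-stimulated genes with a 3′ UTR 3 carry CTTAGAA (against 16.3% of genes not called), so direct matches to it do not account for that list. The siRNA sequences are not given in the sources used here, and comparing them with the motifs would test the hypothesis.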
